A study of Mus musculus with 40 samples.

How the data were processed

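C2C12 is a mouse myoblast line that can be grown as cycling cells or made to differentiate into myotubes. Per the labels, cycling cells were kept in 10% fetal bovine serum, and confluent cells were differentiated in 2% horse serum and then separated from undifferentiated cells with dilute trypsin. The series holds 40 samples. Of these, 12 are promoter arrays, which make 6 replicates of 2 slides each (E2F4, Sin3A and Sin3B, 2 replicates each, differentiated cells). A further 26 are tiling arrays, and 2 are expression samples. The tiling arrays cover 4 factors in differentiated cells (E2F4, RBP2 and Sin3A with 3 arrays each, Sin3B with 4) and chromatin in both states. Pan-acetylated histone H3 (H3ac) and trimethylated lysine 4 of histone H3 (H3K4me3) have 2 arrays per state, and mononucleosomal DNA has 3 arrays of cycling and 2 of differentiated cells.

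Per the labels' protocols, chromatin for the factors was cross-linked with formaldehyde and sonicated to an average of 350 bp, and chromatin for the histone marks was digested with micrococcal nuclease and sonicated. Input and immunoprecipitate were amplified by ligation-mediated PCR, and input was labelled with Cy3 and immunoprecipitate or mononucleosomal DNA with Cy5. Every ratio below is Cy5 over Cy3, so a positive value means enrichment over input. For the mononucleosomal arrays of cycling cells the input's protocol describes differentiated cells, so the source of that input is uncertain, and so is the meaning of those ratios. The labels name no control immunoprecipitation, so the background is the median of each slide. They do not say that replicates came from separate cultures, and p-values then measure only the spread between these samples, which may be technical.

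For the promoter arrays, per the file headers, Agilent Feature Extraction (9.1.3.1, 9.5.1.1 or 9.5.3.1) gave the intensity of each spot in both channels, with the background subtracted after a spatial detrending and the dyes normalised by a method the headers give only as a code. The deposited log10 ratio of the processed intensities was converted to log2, and it equalled the ratio of these intensities wherever a ratio was measured. The deposited value table of the promoter arrays held the same log10 ratios. For the tiling arrays the deposited value table was used. It gives no positions, names or scale, and its values were taken as log10 ratios of Cy5 over Cy3 from their format. Its column medians lay between -0.00666 and 0.0237, so the arrays were close to centred already. For expression, the deposited table holds 1 column of Affymetrix signal intensity per state, on a linear scale. The software behind it is not given in the sources used here.

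Values of exactly 0, which mark spots without a measured ratio, and spots marked by the scanner software as non-uniform or as population outliers were set to missing, and control spots were left out. On the promoter slides between 1.44% and 18.0% of the probes had no ratio. Input was well above background at 62.5% and 59.5% of the probes on the 2 slides of E2F4 replicate 2 and at 64.9% and 63.8% for Sin3B replicate 2. It was so at 79.8% and 85.0% for E2F4 replicate 1 and at 94.3% to 99.0% for the other replicates. The number of arrays limits the precision of every value.

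Each slide's log2 ratios were centred on their median, with no loess and no quantile step. Promoter probes were averaged over windows of 3 consecutive probes within 1000 bp, and the windows were fitted with limma 3.58.1 in R 4.3.3, all 3 factors in one model, against 0. A promoter was called bound when a window had an adjusted p (Benjamini-Hochberg) under 0.05 and a mean log2 ratio of at least 1. Only windows measured in both replicates were tested. Differences between factors were tested with limma contrasts at the window with the highest mean over the 3 factors, at promoters bound by at least 1 of the factors compared. On the tiling arrays single probes took the place of windows, because the probes have no positions here. The chromatin arrays were fitted in a model of their own. Changes of bound probe sets were tested with camera, with the preset correlation of 0.01 and with an estimated one. The sets come from the tiling arrays of the factors, since promoter names could not be carried over to the tiling probes.

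Probe names on the promoter slides gave 17017 single-gene names. Of these, 16158 were matched to current symbols through a RefSeq accession, 344 were current symbols already, 289 matched through a synonym and 226 were kept as given. Another 1500 names join 2 genes that share a divergent promoter, and these are counted but neither named nor ranked. Coordinates are those of the array design. The genome build is not given in the sources used here.

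14 gene lists were fixed before the data were examined, together with the tests, the alternatives in use and the rule for named genes: the 10 bound genes with the highest mean per factor, 4 members of each list with a bound member, the 5 largest differences per contrast, and Sin3a, Sin3b, E2f4, Kdm5a, Myog, Ckm, Ccna2, Mcm5, Cdk1 and Rb1. Kdm5a, which encodes RBP2, was not measured. At most 2 probe identifiers per direction are given where probes have no gene names. List members were tested with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 42 tests. The alternatives were normexp background correction, loess, the deposited value table, a filter on dim inputs, windows of 5 probes, a log2 threshold of 0.58, quantile scaling, scaling to one median absolute deviation, the replicate number as a block, fits on the arrays of a mark alone, and leaving out each array. Normexp started from the mean and background signals instead of the detrended and dye-normalised ones, so it changed more than the background step. Subtracting the local median of 12 by 12 features, leaving out the 2 replicates with the dimmest inputs, the tests of Sin3A and Sin3B at promoters bound by E2F4, the turned signs of 2 replicates, and the overlaps expected within bins of the standard error were added later.

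The fits were tested on simulated data with the spread of the real arrays. At each size 50 windows or probes were raised, with noise independent between them. An adjusted p depends on how many are raised, and the real fits called more, so the shares below are not the power in the real data. For E2F4 on the promoter arrays, 0% of windows raised by a log2 ratio of 1 were recovered, 2% at 2, 30% at 3 and 88% at 4. For E2F4 on the tiling arrays these shares were 0%, 40%, 84% and 94%, and for the change of H3ac they were 0%, 2%, 40% and 72%. Expression values were compared by fold only, among probe sets in the upper 60% of signal in at least 1 state, with no test. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the remaining steps.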

Results

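The series asks, by its title, about a part of Sin3 in permanent gene silencing. Sin3A and Sin3B are scaffolds of histone deacetylase complexes, E2F4 is a repressive E2F transcription factor, and RBP2 (Kdm5a) is a demethylase of methylated lysine 4 of histone H3. Their positions on DNA were measured by chromatin immunoprecipitation on microarrays in differentiated C2C12 cells. Histone marks and mononucleosomal DNA were measured on tiling arrays in cycling and differentiated cells, and expression has 1 column of values for each state. The promoter slides carry 474380 probes, and each tiling array carries 243504 features.

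E2F4 was enriched at promoters of cell cycle genes. Among promoters of single genes, the only ones ranked here, the highest ratio was at Zfp689, a zinc finger gene, with a mean log2 ratio of 6.66 ± 0.55 (SD, n = 2, limma adjusted p = 0.00182) in a window on chromosome 7 from 123545723 to 123546036, centred at an offset of -214 bp from the annotated start. The histone H3 gene H3c8 followed with 6.25 ± 0.59, then Pimreg with 6.06 ± 0.72, Shcbp1 with 6.05 ± 0.49, and Ttf2, a transcription termination factor, with 5.86 ± 0.48. Pclaf, which encodes a partner of the replication clamp, had 5.75 ± 0.56, and Ect2, needed for cytokinesis, had 5.69 ± 0.42. Incenp of the chromosomal passenger complex had 5.67 ± 0.86, the mitotic kinesin gene Kif20a had 5.67 ± 0.34, and Espl1, the gene of separase, had 5.66 ± 0.01. Kif20a's window lies on chromosome 18 from 35000332 to 35000828, at an offset of 166 bp.

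Of 17887 promoters tested, 437 were bound by E2F4, of which 362 belong to single genes and 75 are shared by divergent gene pairs. These had 944 bound windows, and 0 windows lay at a log2 ratio of -1 or below with limma (1032 at an unadjusted p under 0.05). The E2F4 replicates correlated at r = -0.09 over all windows and at 0.55 over the bound windows, where windows are not independent replicates. Bound windows were called partly for a small spread between replicates, which favours the second value. Without E2F4 replicate 1 the count was 0, and without E2F4 replicate 2 it was 147. It was 2297 with normexp, 681 with loess, and 774 with the replicate number as a block.

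**Figure D1:**
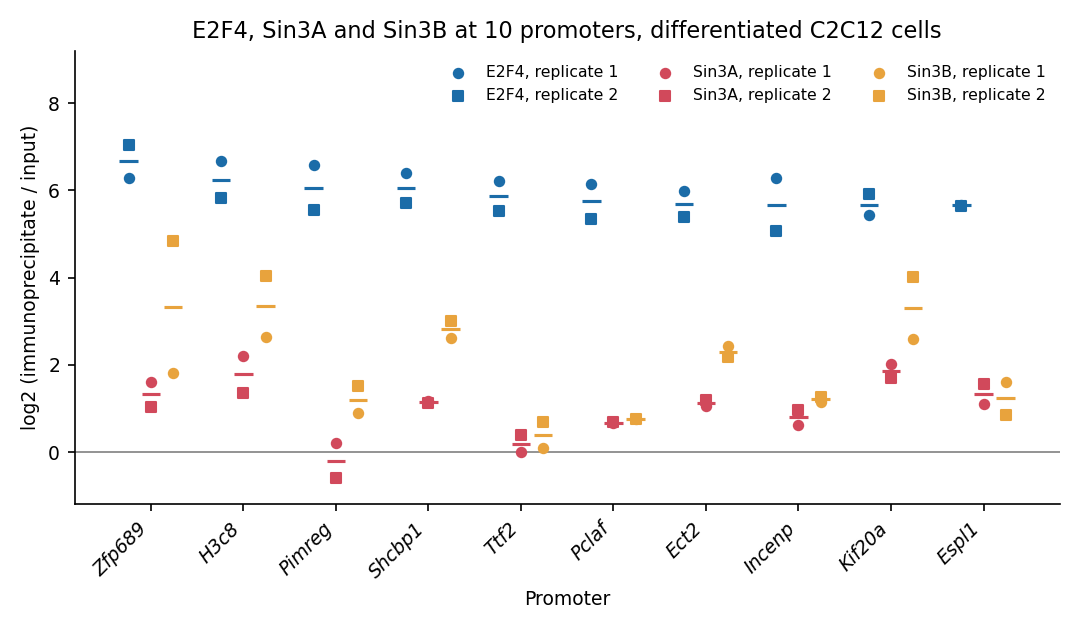
Log2 ratio of immunoprecipitate over input (vertical axis) for E2F4, Sin3A and Sin3B at the 10 single-gene promoters with the highest E2F4 ratio, with 1 point per replicate and a line at the mean of n = 2. E2F4 means run from 5.66 at Espl1 to 6.66 at Zfp689, above both Sin3 proteins at each promoter.

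Mitosis genes made up the best covered list: 40 of 54 measured members were bound by E2F4, against 1.19 expected (Fisher's exact test, adjusted p = 6.11e-54), and 53 were bound when adjusted over the list alone. Ect2, Incenp, Kif20a and Espl1 led it. Of the DNA replication genes 16 of 53 were bound (1.17 expected, adjusted p = 3.29e-13), and 30 when adjusted over the list alone. They include Rrm2, a subunit of ribonucleotide reductase (4.62 ± 1.42), the phosphatase gene Cdc25a (4.43 ± 0.28), the activator E2f3 (4.34 ± 0.28) and the clamp loader gene Rfc4 (4.06 ± 0.18). DNA repair genes were bound at 11 of 31 members (0.683 expected, adjusted p = 4.08e-10), and 19 when adjusted over the list alone. Among them are the helicase gene Blm (4.28 ± 0.24), the Fanconi anaemia genes Fancb (4.01 ± 0.43) and Fanci (3.40 ± 1.32), and Rad54b (3.88 ± 0.48). Genes of replication-coupled chromatin were bound at 8 of 24 members (0.529 expected, adjusted p = 2.91e-07), and 10 when adjusted over the list alone, with H2ax (4.41 ± 0.79), Uhrf1 (4.26 ± 1.47), the histone chaperone gene Asf1b (3.68 ± 0.94) and the cohesin gene Smc1a (3.63 ± 0.06).

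Olfactory receptor genes were bound at 0 of 739 members, against 16.3 expected (adjusted p = 8.41e-07). Of the Sin3 complex and E2F family genes 3 of 31 were bound (adjusted p = 0.212), and 7 when adjusted over the list alone. The 3 were Mybl2 (3.90 ± 0.31), Lin52 (3.19 ± 0.47) and Sin3a (2.62 ± 0.51), while Brms1l, at 2.30 ± 0.61, passed only over the list alone. Myogenic regulators were bound at 1 of 33 members (adjusted p = 1), which was Id1, an inhibitor of myogenic factors (2.55 ± 0.04). Rb1 (1.82 ± 0.11), Musk (1.60 ± 0.44) and Id3 (1.32 ± 0.33) did not pass. Oxidative phosphorylation genes were bound at 2 of 58 members, Ndufs8 (2.92 ± 0.14) and Cox8a (2.61 ± 0.45), and 3 when adjusted over the list alone, with Atp5o (2.00 ± 0.41) the added gene and Atp5h (1.67 ± 0.59) not among them. Ribosomal protein genes were bound at 1 of 59 members, Rpl35 (2.87 ± 0.32), and Rpl24 (1.81 ± 0.44), Rps20 (1.72 ± 0.03) and Rpl3 (1.56 ± 0.70) did not pass. For the myogenic and ribosomal lists 1 member each was bound when adjusted over the list alone. Sarcomere genes (0 of 48), fibroblast markers (0 of 21), adipocyte markers (0 of 11), bone and cartilage markers (0 of 11) and neuronal markers (0 of 12) held no bound member with limma, over all genes or adjusted over the list alone, and 6847 windows of all promoters passed an unadjusted p under 0.05.

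**Figure D2:**
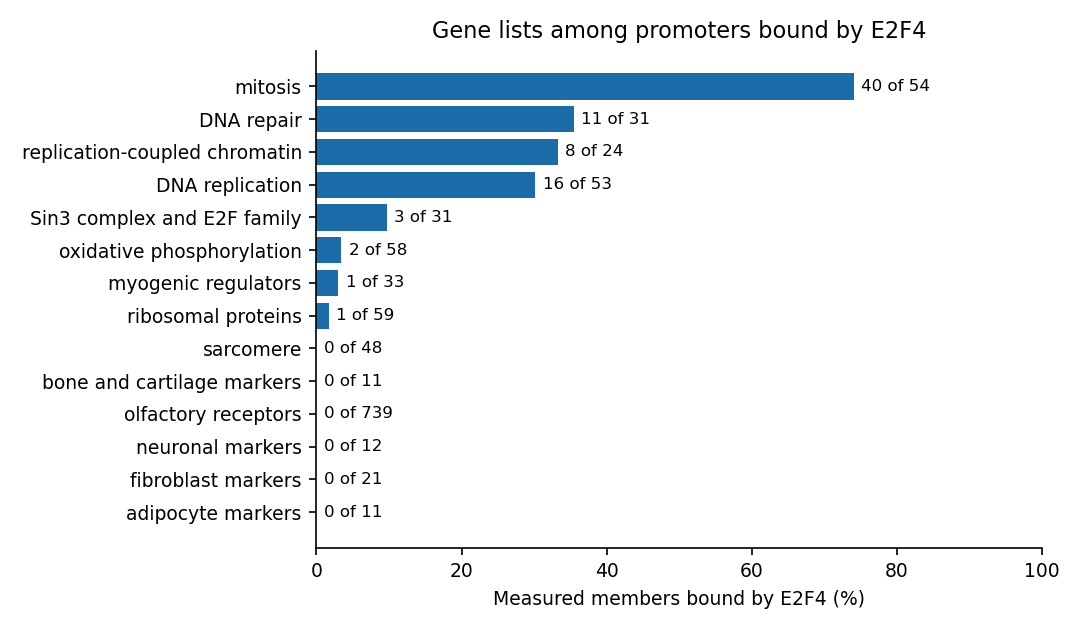
Percentage of measured members bound by E2F4 (horizontal axis) for each of the 14 gene lists, with the number bound beside each bar. The mitosis list stands highest with 40 of 54 members, and the olfactory receptors have 0 of 739.

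At genes named in advance, Mcm5, a subunit of the replicative helicase, had ratios of 3.37 ± 0.66 for E2F4 (limma adjusted p = 0.00432), 1.52 ± 0.08 for Sin3A and 2.69 ± 0.15 for Sin3B. Cdk1, the mitotic kinase gene, had 2.27 ± 1.33 for E2F4 (adjusted p = 0.173), 1.31 ± 0.18 for Sin3A and 1.48 ± 0.84 for Sin3B. Ccna2, the gene of cyclin A, had 1.84 ± 1.11 for E2F4 (adjusted p = 0.310), 0.83 ± 0.47 for Sin3A and 0.94 ± 0.49 for Sin3B. The muscle genes Myog and Ckm had E2F4 ratios of 0.38 ± 0.34 and 0.37 ± 0.07, and Sin3B ratios of 1.66 ± 1.05 and 0.58 ± 0.31. Their Sin3A ratios were -0.14 ± 0.88 and -0.02 ± 0.13. Sin3b had 0.90 ± 0.01 for Sin3A, -0.15 ± 0.39 for E2F4 and 0.77 ± 0.30 for Sin3B, and E2f4 had 0.08 ± 0.31, 0.46 ± 0.23 and 0.73 ± 0.28. None of the Sin3A and Sin3B values of these genes passed the test over all windows.

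Sin3A and Sin3B had 0 bound promoters each among 18015 and 17979 tested with limma, where the lowest adjusted p was 0.449 for Sin3A and 0.216 for Sin3B. At an unadjusted p under 0.05, 4858 windows lay at a log2 ratio of 1 or above for Sin3A and 16348 for Sin3B, with 22079 and 6593 at -1 or below. Overlap of all 3 factors was therefore 0. Adjusted over the list alone, Sin3B was bound at 29 of 54 mitosis genes and below -1 at 1, at 3 of 53 replication genes (Mcm5, Rfc4 and Rrm2) and at 2 of 58 oxidative phosphorylation genes (Ndufa9 and Ndufs7). Sin3A was bound at 2 mitosis genes, Smc2 and Smc4, which encode the core of condensin. Lists other than those of mitosis, DNA repair, replication and oxidative phosphorylation had 0 for both proteins with limma. Those of these genes that fall outside the naming rule were chosen after their values were seen. Normexp gave 635 promoters for Sin3A, the replicate block gave 176 for Sin3B, and leaving out the 2 replicates with the dimmest inputs gave 418 for Sin3A, with 689 windows bound and 4859 windows at -1 or below.

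At the promoters bound by E2F4, both Sin3 proteins were enriched. This test was chosen after the counts above were seen, and its genes were named after their values were seen. Its p-values use the same standard error, pooled over all 3 factors, as the E2F4 call. That call favours windows where the standard error is small, so the Sin3 p-values here are likely too small. Among the 437 promoters, Sin3A was called at 48 and Sin3B at 193 with limma (106 and 202 at an unadjusted p under 0.05), and the ratio was above 0 at 84.9% and 85.4% of them. This share was not computed at other promoters. Those also had positive Sin3A means in the 500 bp after the start (0.21 and 0.41). Smc2 had 2.34 ± 0.15 for Sin3A (adjusted p = 0.0105), 3.46 ± 0.10 for Sin3B (adjusted p = 2.66e-04) and 3.60 ± 0.01 for E2F4. Smc4 had 2.16 ± 0.04, 2.26 ± 0.10 and 3.23 ± 0.05, in a window at an offset of -4666 bp. Oscp1 had 2.27 ± 0.03 for Sin3A and 3.29 ± 0.14 for Sin3B, and Hrob, a recombination factor gene, had 2.16 ± 0.12 and 2.86 ± 1.00. The mitotic kinase gene Aurkb had 2.02 ± 0.07 and 2.35 ± 0.73, and Kif2c, a kinesin gene, had 1.56 ± 0.21 and 2.98 ± 0.06. Both proteins were called at 44 promoters, against 21.2 expected of independent lists and 23.7 within 20 bins of the standard error, which the calls of both proteins share.

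Without Sin3A replicate 1, Sin3A replicate 2 or E2F4 replicate 1 the Sin3A count was 0. The Sin3B count was 0 without E2F4 replicate 1, 88 without E2F4 replicate 2 and 117 without Sin3B replicate 1. Since no promoter was bound by E2F4 without E2F4 replicate 1, nothing was left there to test for either Sin3 protein. Normexp gave 196 for Sin3A and 72 for Sin3B, the block gave 81 for Sin3A, loess gave 25, and the filter on dim inputs gave 18. Over all windows E2F4 replicate 2 correlated with Sin3B replicate 2 at r = 0.57, and with the Sin3A replicates at -0.34 and -0.39. Sin3B replicate 2 correlated with the Sin3A replicates at -0.33 and -0.40. These replicates of E2F4 and Sin3B have dim inputs and share a software version, and the dyes stated in the labels set the direction of each ratio. In the 500 bp before the start of mitosis genes, a list fixed before the data were examined, E2F4 replicate 2 had a mean log2 ratio of 2.41 (0.02 at other genes) and replicate 1 had 2.89 (0.22), so the direction of replicate 2 as labelled was kept. Sin3B replicate 2 had 0.31 there (-0.19 at other genes) and replicate 1 had 0.92 (-0.09), a smaller difference. Over windows bound by E2F4, Sin3B replicate 2 correlated at r = 0.64 with Sin3B replicate 1 and at 0.36 and 0.34 with the Sin3A replicates. Over all windows the 2 Sin3B replicates correlated at 0.06. The E2F4 call uses a spread pooled over the replicates of all 3 factors, so bound windows favour agreement of the Sin3B replicates. The value of 0.64 is therefore no independent evidence of direction. The values of 0.36 and 0.34 go with the labelled direction of Sin3B replicate 2, but come from the same chosen windows. Its correlations with Sin3A over all windows go the other way. The direction of Sin3B replicate 2 therefore stays less certain. With the sign of E2F4 replicate 2 turned, 0 promoters were bound by any factor with limma (1979 windows at 1 or above for E2F4 at an unadjusted p under 0.05). With that of Sin3B replicate 2 turned, 338 were bound by E2F4, and 0 among them were called for either Sin3 protein with limma (48 for Sin3A and 2 for Sin3B unadjusted).

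Against E2F4 itself, the Sin3 ratios were lower at promoters that were chosen for a high E2F4 ratio, which favours E2F4 in this comparison. The E2F4 call also favours a small standard error, which the contrasts share where they use the same window. Sin3A was lower at 394 of 437 promoters and higher at 0 with limma (399 in either direction at an unadjusted p under 0.05), with a median difference of -2.53. Sin3B was lower at 341 and higher at 0 (357 unadjusted), with a median of -2.15. The 5 largest Sin3A differences were at Pimreg (-6.26 ± 0.57, SE), the immediate early gene Ier5 (-5.69 ± 0.65), Ttf2 (-5.68 ± 0.53), Zfp689 (-5.34 ± 0.85) and Pclaf (-5.08 ± 0.51). Those of Sin3B were at Depdc1a (-5.52 ± 0.60), Ttf2 (-5.48 ± 0.53), Pclaf (-4.99 ± 0.51), Pimreg (-4.86 ± 0.57) and the kinase gene Pak4 (-4.85 ± 0.60). Sin3A and Sin3B differed at 0 of the 437 promoters with limma (65 at an unadjusted p under 0.05, median -0.43), 7 without Sin3B replicate 1, 17 with the filter on dim inputs and 5 with the block. The Sin3A arrays were read with a software version that no E2F4 or Sin3B array shares. Version and factor therefore cannot be told apart for Sin3A against E2F4 or for Sin3A against Sin3B. For Sin3B against E2F4 the median within version 9.1.3.1 was -2.60 (436 of 437 promoters lower), and within version 9.5.1.1 it was -2.21 (430 of 436 lower). These medians were taken at the bound window with the highest E2F4 mean, not at the window of the contrast, which favours E2F4 further. The version 9.5.1.1 value rests on Sin3B replicate 2, whose direction is less certain. Neither it nor the contrast was computed with that sign turned. With the replicate number as a block, which for E2F4 and Sin3B is also the version, 588 promoters differed in the contrast. Without E2F4 replicate 1 both counts against E2F4 were 0, and without E2F4 replicate 2 they were 147 for Sin3A and 140 for Sin3B. Nothing was left to compare without E2F4 replicate 1, since no promoter was bound by E2F4 there. With the block the Sin3A count was 634.

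Around the start site, E2F4 peaked just upstream at its bound genes, with a mean log2 ratio of 2.65 and 2.24 in the 500 bp before the start in replicates 1 and 2. Sin3A was highest in the 500 bp after it, at 0.64 and 0.90, against 0.21 and 0.41 at other promoters. Sin3B replicate 1 was also highest there, at 1.05 against 0.05. Sin3B replicate 2 had 0.53 there against -0.28 at other promoters, and 0.61 against 0.19 in the next 500 bp. Relative to other promoters, replicate 2 thus also stood highest in the first 500 bp after the start. The downstream differences that follow are not taken relative to other promoters. The mean from 500 to 2500 bp downstream minus the mean within 500 bp of the start was -0.80 ± 0.08 (SD, n = 2) for Sin3A, -1.71 ± 0.60 for E2F4 and -0.30 ± 0.40 for Sin3B. From 200 to 1500 bp downstream the 2 replicates had -0.43 and -0.50 for Sin3A, -1.65 and -1.10 for E2F4, and -0.28 and 0.09 for Sin3B. An exact permutation test between any pair gave p = 0.333, two-sided, which is the smallest that 2 against 2 replicates allow.

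**Figure D3:**
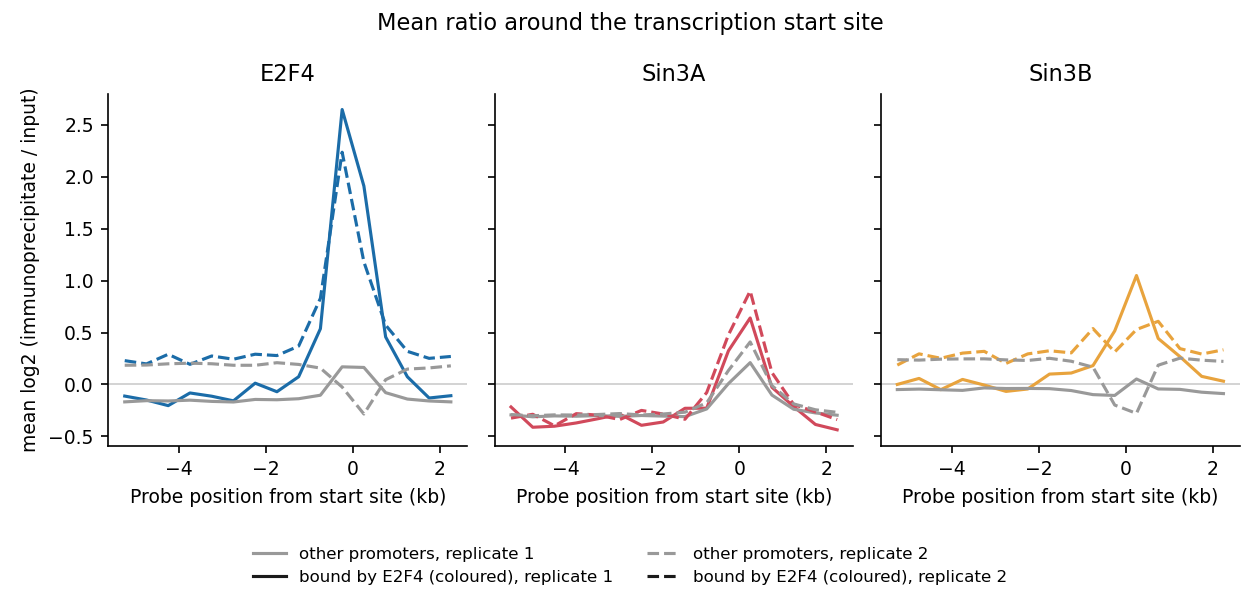
Mean log2 ratio (vertical axis) by position from the start site in kb (horizontal axis, bins of 500 bp) for each replicate, at genes bound by E2F4 (coloured) and at other promoters (grey). E2F4 peaks at 2.65 and 2.24 just upstream of the start, and the Sin3A replicates peak at 0.64 and 0.90 just downstream.

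On the tiling arrays, E2F4 was bound at 2509 probes (median log2 ratio 2.89), RBP2 at 3063 (1.64), Sin3A at 260 (3.90) and Sin3B at 3101 (1.94). These probes carry no gene names or positions here. The ratio was at -1 or below at 67 probes for E2F4, 327 for RBP2, 227 for Sin3A and 659 for Sin3B. Features 3191 (7.12 ± 0.32, SD, n = 3) and 130699 (6.83 ± 1.34) had the highest E2F4 ratios, and features 70528 (6.97 ± 1.40) and 31538 (6.86 ± 1.57) the highest RBP2 ratios. Feature 212289 was among the highest 2 for both Sin3A (6.78 ± 0.63, beside feature 69983 with 6.85 ± 1.28) and Sin3B (8.01 ± 1.38, n = 4, beside feature 229644 with 8.31 ± 1.19).

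Replicates correlated at r between 0.03 and 0.46 for E2F4, 0.47 and 0.56 for RBP2, 0.40 and 0.50 for Sin3A, and -0.14 and 0.60 for Sin3B. E2F4 replicate 1 correlated at -0.54 to -0.35 with the H3ac arrays and at -0.42 to -0.32 with the Sin3A arrays. E2F4 replicates 2 and 3 correlated with all of these at 0.09 to 0.36. The direction of E2F4 replicate 1 was not tested on the tiling arrays. The E2F4 sets, overlaps and contrasts include it, except in the fits that leave it out. The E2F4 count was 1600 without E2F4 replicate 2. The Sin3B count was 1534, 1952 and 1330 without Sin3B replicate 2, 3 and 4, and 1614 after scaling to one median absolute deviation. The RBP2 count was 0 when any 1 of the 3 RBP2 arrays was left out, 1257, 1423 and 1066 without Sin3A replicate 1, 2 and 3, 756 without Sin3B replicate 4, and 6543 without E2F4 replicate 1. It was 4903 with quantile scaling, where 8413 probes lay at -1 or below, and 6702 after scaling to one median absolute deviation, with 2148 below. Without E2F4 replicate 1, 952 probes lay at -1 or below for E2F4, 6564 for RBP2, 1362 for Sin3A and 2421 for Sin3B, so the counts of probes below -1 depend on that array. The Sin3A count was 0 when any 1 of the RBP2 or Sin3A arrays or Sin3B replicate 4 was left out, 117 without Sin3B replicate 3, 1408 without E2F4 replicate 1, 1677 with quantile scaling and 0 after scaling to one median absolute deviation. With the replicate number as a block, the RBP2 and Sin3A counts were both 0.

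Probes bound by Sin3B overlapped those of each other factor beyond the number independent lists would share. E2F4 and Sin3B shared 1013 probes (44.9 expected, or 73.8 within 100 bins of the standard error, which the calls of all factors share), RBP2 and Sin3B 591 (44.8 or 46.8 expected), and Sin3A and Sin3B 231 of the 252 tested Sin3A probes (4.18 or 8.95 expected), each with a p below the smallest the software can print (Fisher's exact test, 6 pairs). RBP2 and Sin3A shared 202 (3.55 or 3.89 expected), and E2F4 and Sin3A shared 30 (3.70 or 3.43 expected, adjusted p = 2.79e-18). E2F4 and RBP2 shared 35, against 38.4 or 33.6 expected (adjusted p = 0.681). These p-values take the lists and the single probes as independent. They do not allow for the shared standard error or for a correlation between probes. On the E2F4 arrays the probes bound by RBP2 had median log2 ratios of -0.79, 0.46 and 0.25. Probes bound by E2F4 had medians of 0.63, 1.46, 1.56 and 1.22 on the 4 Sin3B arrays and of 0.52, 0.94 and 0.63 on the 3 Sin3A arrays. Probes bound by Sin3A had a median of -0.06 on E2F4 replicate 1, 3.60 and 4.14 on the other two E2F4 arrays, and 2.43 on mononucleosomal DNA of cycling replicate 2. Where a bound set rests on single arrays, as given above for RBP2 and Sin3A, its overlaps rest on them too.

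**Figure D4:**
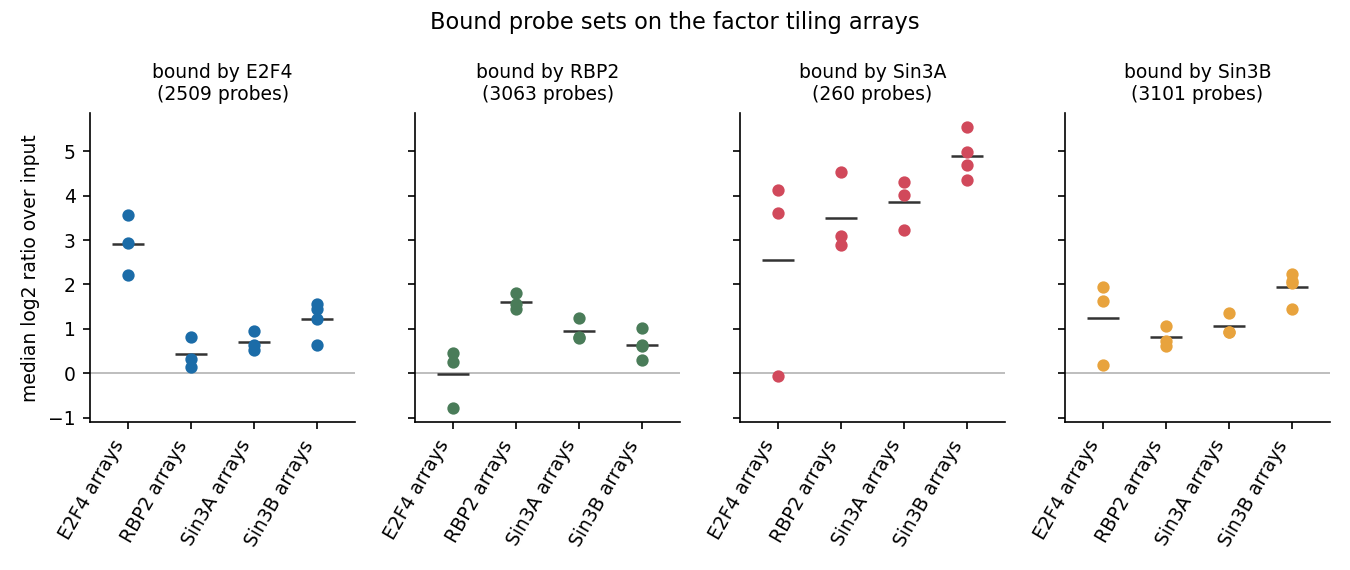
Median log2 ratio over input (vertical axis) of the probes bound by E2F4, RBP2, Sin3A and Sin3B on each factor array (points), with a line at the mean of the arrays of a factor. Probes bound by Sin3A have medians of at least 2.89 on each RBP2, Sin3A and Sin3B array but -0.06 on E2F4 replicate 1.

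Direct contrasts were run at probes bound by at least 1 factor of each pair. Sin3A was higher than Sin3B at 3 probes and lower at 153. Sin3B was higher than E2F4 at 932 and lower at 1490, RBP2 was higher than E2F4 at 2100 and lower at 2275, RBP2 was higher than Sin3B at 689 and lower at 988, and Sin3A was higher than E2F4 at 63 and lower at 2017. RBP2 and Sin3A differed at 0 of 2928 probes with limma (338 at an unadjusted p under 0.05). The balance of higher and lower calls moved with the scaling. With quantile scaling and with scaling to one median absolute deviation, the higher and lower counts were 8 and 57 or 0 and 35 for Sin3A against Sin3B, 609 and 630 or 286 and 1831 for Sin3B against E2F4, and 2981 and 1467 or 4355 and 2465 for RBP2 against E2F4. They were 111 and 283 or 1920 and 440 for RBP2 against Sin3B, and 888 and 999 or 0 and 2389 for Sin3A against E2F4. For RBP2 against Sin3A they were 17 and 9 or 1 and 0.

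Single arrays decide several of these directions. The 2100 probes with RBP2 above E2F4 fell to 0 when any 1 RBP2 array was left out, where 1918, 1980 and 2161 probes in all remained called for RBP2 replicates 1, 2 and 3, each with RBP2 below E2F4. They were 864, 986 and 736 without Sin3A replicates 1, 2 and 3, 1372 without Sin3B replicate 3 and 516 without Sin3B replicate 4, and the total of 4375 was 2879 without Sin3A replicate 3 and 2613 without Sin3B replicate 4. The 689 probes with RBP2 above Sin3B were 1, 1 and 3 without RBP2 replicates 1, 2 and 3, of totals of 367, 419 and 831. They were 444 without Sin3A replicate 3, 316 and 1112 without Sin3B replicates 1 and 2, 526 of 1170 without Sin3B replicate 3, and 323 of 920 without Sin3B replicate 4. The 63 probes with Sin3A above E2F4 were 0 when any 1 RBP2 array, any 1 Sin3A array or Sin3B replicate 4 was left out, 31 without Sin3B replicate 3, and 148, 190 and 204 without E2F4 replicates 1, 2 and 3.

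The 932 probes with Sin3B above E2F4 were 415 without E2F4 replicate 1, 1481 without Sin3B replicate 1, 538 without Sin3B replicate 2 and 517 without Sin3B replicate 4. The 3 probes with Sin3A above Sin3B were 0 when any 1 RBP2 or Sin3A array or Sin3B replicate 3 or 4 was left out, and 5 without E2F4 replicate 3 or Sin3B replicate 2. The Sin3A against Sin3B total of 156 was 99 without RBP2 replicate 2, 53, 103 and 26 without Sin3A replicates 1, 2 and 3, 503 without Sin3B replicate 1 and 96 without Sin3B replicate 4. The RBP2 against Sin3A total of 0 was 24 without E2F4 replicate 3, 6 without Sin3A replicate 1, and 9, 18, 10 and 2 without Sin3B replicates 1, 2, 3 and 4.

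Between cycling and differentiated cells, H3ac rose at 717 tiling probes and fell at 886, and H3K4me3 rose at 134 and fell at 51. Mononucleosomal DNA changed at 0 probes with limma (8273 higher and 4997 lower at an unadjusted p under 0.05, lowest adjusted p = 0.840). For H3ac, features 216249 and 172679 changed by -6.69 ± 0.88 (SE) and -6.24 ± 0.81 on the log2 scale, and features 202602 and 125089 by 5.41 ± 1.00 and 5.18 ± 0.41. For H3K4me3, features 95483 and 18345 changed by -5.66 ± 0.41 and -5.32 ± 0.51, and features 51149 and 197779 by 5.85 ± 0.59 and 5.61 ± 0.57. Scaled to one median absolute deviation, H3ac rose at 221 and fell at 678, and with quantile scaling H3K4me3 rose at 115 and fell at 95. With only the arrays of the mark in the fit, both counts were 0.

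Single arrays decide these counts. The H3ac total of 1603 was 163 (99 rose and 64 fell) and 194 (53 rose and 141 fell) without H3ac cycling replicates 1 and 2, 981 and 77 without H3ac differentiated replicates 1 and 2, 652, 798 and 807 without mononucleosomal cycling replicates 1, 2 and 3, and 499 without either mononucleosomal array of differentiated cells. The H3K4me3 total of 185 was 0 without either of the latter, 47, 64 and 71 without mononucleosomal cycling replicates 1, 2 and 3, and 114 without either H3ac array of cycling cells. It was 3804 (2986 rose and 818 fell) and 1336 (1260 rose and 76 fell) without H3K4me3 cycling replicates 1 and 2. Without H3K4me3 differentiated replicate 1 it was 2082, with the balance turned over (440 rose and 1642 fell), and without replicate 2 it was 2619 (2046 rose and 573 fell). The source name of H3K4me3 cycling replicate 1 says H3 acetylation, against its title. The array was grouped by title, and over all probes it correlated at r = 0.37 with H3K4me3 cycling replicate 2 and at 0.16 and 0.17 with the H3ac cycling arrays, which correlated at 0.75 with each other. Mononucleosomal DNA changed at 8 probes without differentiated replicate 1.

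At probes bound by E2F4 in differentiated cells, H3ac was lower in differentiated than in cycling cells. Over the 2354 such probes tested, the mean log2 ratio was 0.81 in cycling and 0.16 in differentiated cells, a change of -0.63 relative to the other probes (limma's camera, adjusted p = 4.82e-17), with p = 0.0587 with an estimated correlation. The per-array medians were 0.88 and 0.75 in cycling cells and -0.04 and 0.31 in differentiated cells. H3K4me3 changed by -0.36 there (camera, adjusted p = 2.52e-07, and p = 0.204 with an estimated correlation). Its array medians there were 0.06 and 0.22 in cycling cells and -0.23 and -0.02 in differentiated cells. In median the mark was thus barely enriched at these probes in either state. The differentiated H3K4me3 arrays correlated at r = 0.25 with each other. Mononucleosomal DNA changed by 0.02 (limma's camera, adjusted p = 0.714), where the mean is positive and the camera test points down, and the mean was -0.01, -0.05 and -0.03 without cycling replicate 2, cycling replicate 3 and differentiated replicate 2. The H3ac change was -0.81 to -0.47 and the H3K4me3 change -0.50 to -0.21 when each array was left out.

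Probes bound by RBP2 changed in H3ac by -0.58 (camera, adjusted p = 6.90e-18, and p = 0.0626 with an estimated correlation) and in H3K4me3 by -0.50 (adjusted p = 4.97e-11, and p = 0.135 with an estimated correlation). Mean H3K4me3 at the probes bound by RBP2 was 0.05 in cycling and -0.37 in differentiated cells. With cycling array medians of -0.08 and -0.03, the mark was not enriched there in cycling cells, so no loss of it can be read from the change. Probes bound by Sin3B changed in H3ac by -0.26 (adjusted p = 0.00154, and p = 0.388 with an estimated correlation) and in H3K4me3 by -0.74 (adjusted p = 1.84e-21). For the latter, p = 0.0290 with an estimated correlation, or 0.250 after adjustment over 12 tests. Probes bound by Sin3A changed in H3ac by 0.08 (adjusted p = 0.954) and in H3K4me3 by -1.30 (adjusted p = 6.90e-18, and p = 0.203 with an estimated correlation). Mononucleosomal DNA changed by -0.17 at probes bound by RBP2 (adjusted p = 1.11e-05, and p = 0.293 with an estimated correlation), by 0.03 at those of Sin3A (adjusted p = 0.690; the test points down) and by 0.08 at those of Sin3B (adjusted p = 0.397). No adjusted p of these 12 tests was under 0.05 with an estimated correlation, and differences between the sets were not tested.

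Of the probes where H3ac fell, 39 were bound by E2F4 (10.5 expected, Fisher's exact test, adjusted p = 8.38e-11) and 29 by Sin3B (13.8 expected, adjusted p = 0.00161). RBP2-bound probes were among them 6 times (13.3 expected, adjusted p = 0.160). Of the probes where H3ac rose, 1 was bound by E2F4 (8.04 expected, adjusted p = 0.0252) and 0 by RBP2 (10.8 expected, adjusted p = 3.00e-04). Fisher's test takes probes as independent, while camera estimated a correlation of 0.15 between probes of the E2F4 set. The calls of change rest on single arrays and are lost with only the arrays of the mark, as given above. These overlaps were not counted again in those fits.

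**Figure D5:**
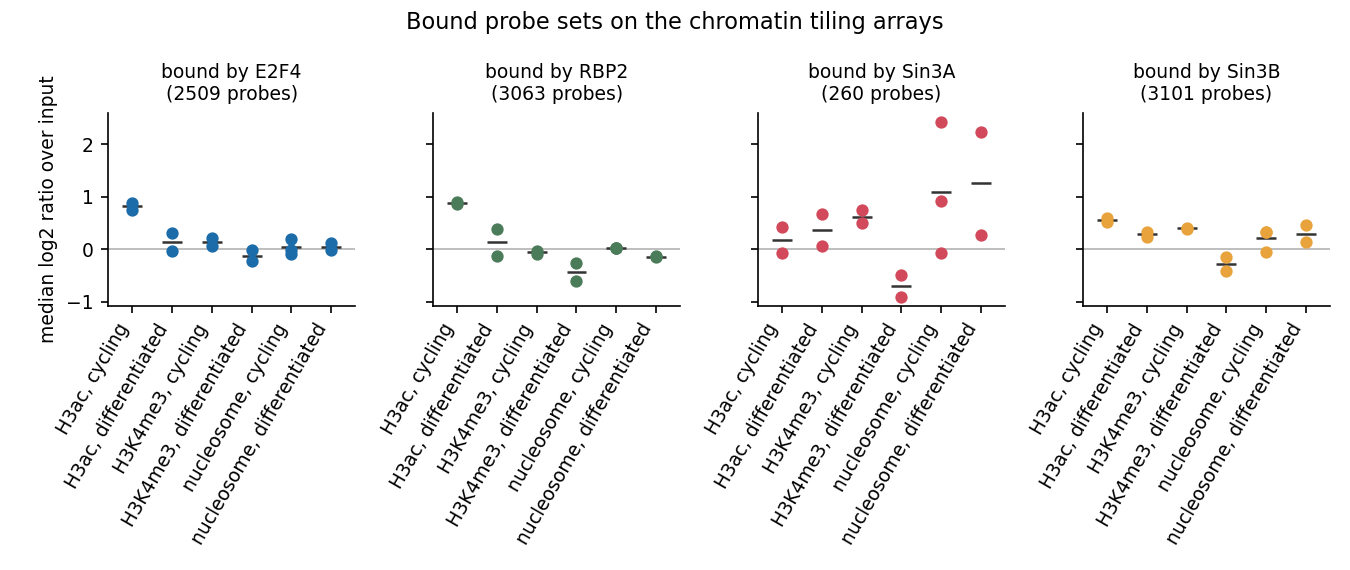
Median log2 ratio over input (vertical axis) of the bound probe sets on each chromatin array (points) in cycling and differentiated cells, with a line at the mean of a group. H3ac at probes bound by E2F4 has medians of 0.88 and 0.75 in cycling and -0.04 and 0.31 in differentiated cells.

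Expression has 1 column of values per state, so no difference was tested. The protocol speaks of triplicate experiments, and whether a column stands for 1 array or a mean of several is not given in the sources used here. Among 14608 probe sets in the upper 60% of signal, 1016 were higher by at least 2-fold in differentiated cells and 1368 were lower, 2384 in all. The probe sets carry no gene names here. Probe set 1427520_a_at read 22.0 signal units in cycling and 7606 in differentiated cells, 1427868_x_at read 25.2 and 8122, and 1427760_s_at read 7785 and 127. The low signal of each lies under the level of the filter (204 in cycling and 192 in differentiated cells) and was not shown to be above background, so no fold or order is given for them. Probe set 1438009_at read 7430 and 280.3, a log2 difference of -4.73. The median difference of the 14608 probe sets was -0.04. Labelled spikes bioB, bioC and bioD, which are added to each sample in equal amount by the array's design, were higher by a median of 1.01 (0.86 to 1.13), and the cre spikes by 0.44. Probe sets for Gapdh had a median difference of 0.14 and those for beta-actin -0.63 (-1.12 to -0.47), and with quantile scaling these medians were 0.02 and -0.67.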

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

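Of the tests below, the reading of H3ac at probes bound by Sin3A, the reading of the promoter arrays other than Sin3B replicate 2, the reading of mononucleosomal arrays, and everything done with a local median or at promoters bound by E2F4 were chosen only after the result was seen.

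On the tiling array of Sin3B replicate 3, 20.8% of the features had no measured ratio, against 3.04%, 2.51% and 3.15% on the other Sin3B arrays. The gap to the nearest array made up 0.965 of the whole range, above Dixon's 95% critical value for 4 samples. This was 1 of 9 measures examined for this group, and a share of 0.05 passes by chance at each measure, so the chance of at least 1 pass in 9 is larger. Without this array 1952 probes were bound by Sin3B, against 3101.

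At probes bound by E2F4, H3ac was lower in differentiated than in cycling cells, a call that is lost with an estimated correlation (p = 0.0587, and 0.0627 with the local median subtracted). A trend across the slide is argued against, because the change was -0.626 with the local median of each array subtracted and -0.633 without it. A fall at every set of enriched probes stays open. In mean change, not taken relative to the other probes, probes bound by RBP2 and Sin3B fell by 0.60 and 0.28. The change of 0.0587 at probes bound by Sin3A decides nothing, since that set had little H3ac in cycling cells, with medians of -0.07 and 0.43. A weaker H3ac immunoprecipitation in differentiated cells stays open too: among probes enriched on 1 cycling array, those bound by E2F4 kept 14.8% of the ratio and other probes 19.2%, a gap of 4.37 percentage points, and 12.9 points with the other cycling array. A loss of acetylation at E2F4 targets with differentiation is an untested hypothesis, and these open explanations could account for the values in part or in full.

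Sin3A and Sin3B were enriched at promoters bound by E2F4. An enrichment of start-site probes in any immunoprecipitation is argued against as the whole cause. The median at 361 of these promoters lay at percentile 100 of 10000 random lists matched on position and input signal on each Sin3 array. It was 0.56 and 0.71 on the Sin3A arrays, against 0.19 and 0.31 for the random lists. On the Sin3B arrays it was 0.97 and 0.91, against -0.08 and -0.31. Part of the Sin3A signal is thus also found at matched start sites. Conditions shared by the dim replicates of E2F4 and Sin3B are argued against as the whole cause, because the median was 0.562 or more on both Sin3A arrays and on Sin3B replicate 1. The design gives no cells in which E2F4 or Sin3 is absent, so no biological explanation was tested. That Sin3 proteins may be recruited with E2F4 in myotubes remains a hypothesis, and the random lists do not cover reads of open chromatin at cell cycle genes.

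Probes bound by Sin3A on the tiling arrays were also high on arrays of other material. A slide trend is argued against, since 91.5% of these probes were still bound with the local median subtracted. Probes that read bright on some arrays whatever was hybridised remain open: the median was 2.43 on mononucleosomal DNA of cycling replicate 2 and 2.23 on that of differentiated replicate 2. On the H3ac arrays it lay between -0.07 and 0.67 and on the H3K4me3 arrays between -0.91 and 0.74, so these probes were not bright on every array. On mononucleosomal DNA the median was 0.92 and -0.08 on the other 2 cycling arrays and 0.28 on the other differentiated one, and the input of the cycling arrays is uncertain. The overlap of Sin3A with RBP2 and Sin3B may therefore come in part from such probes (2.43), and no biological explanation was tested for it.

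Other splits of the same arrays were counted for each contrast. For Sin3A against Sin3B, with 156 probes, chance is not excluded: 2 of 35 splits gave as many. The highest other split, Sin3B replicates 2, 3 and 4 against Sin3B replicate 1 with the Sin3A arrays, gave 602, which points to a structure of the samples. For Sin3B against E2F4 1 of 35 splits, the real one and the smallest share possible, gave 2422, and the highest other gave 1240. For RBP2 against Sin3B 1 of 35 splits, the real one, gave 1677, but a split that joins Sin3B replicate 1 to the RBP2 arrays gave 1666, so a difference of the other Sin3B arrays from Sin3B replicate 1 and RBP2 gives nearly the same count. Without RBP2 replicate 1 the real count was 367, and this contrast is not read as a difference between the factors alone. The splits of 3 against 3 arrays are too few, with 10 in all. Their real and highest other values were 4375 and 1002 for RBP2 against E2F4, 2080 and 29 for Sin3A against E2F4, and 0 and 0 for RBP2 against Sin3A, where each of the 10 splits gave 0.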

How the results depend on the processing

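Alternatives with the local median, without the 2 dim replicates, with an estimated correlation after the local median, and the tests of Sin3A and Sin3B among promoters bound by E2F4 were chosen only after the results were seen. Of 462 alternative values, 329 kept their direction and their side of the threshold or stayed within 1.5 times, 126 moved, 4 lost the call and 3 changed sign. Outside leaving out arrays, 140 of 194 were kept, among them all with a threshold of 0.58 (26 of 26), windows of 5 probes (16 of 16) and the deposited value table (10 of 10), and 25 of 26 with the local median. The deposited value table holds the same ratios, and this alternative differs in keeping values of 0 and marked spots. It gave 353 promoters bound by E2F4 and 66 called for Sin3A among its promoters, against 437 and 48. Some of the kept values could hardly move. The threshold of 0.58 left the 437 promoters bound by E2F4 unchanged. A count of 0 that stayed 0 was also taken as kept. Where no cause is given below, the cause was not tested. Normexp gave 635 promoters bound by Sin3A, 2297 by E2F4, 104 differing between Sin3A and Sin3B, 708 between Sin3A and E2F4 and 1034 between Sin3B and E2F4, with 196 and 72 for Sin3A and Sin3B among promoters bound by E2F4. Loess gave 681 for E2F4, 641 and 540 for the contrasts of Sin3A and Sin3B with it, and 25 for Sin3A among its promoters. The filter on dim inputs gave 18 for the latter and 17 for Sin3A against Sin3B there. Without E2F4 replicate 2 and Sin3B replicate 2 the counts were 418 for Sin3A (with 4859 windows at -1 or below), 691 for E2F4 (357 windows below), 657 and 528 for the contrasts with E2F4, and 166 for Sin3A among its promoters. Quantile scaling of the tiling arrays gave 4903 probes bound by RBP2, 1677 by Sin3A, and 65, 1239, 394 and 26 for Sin3A against Sin3B, Sin3B against E2F4, RBP2 against Sin3B and RBP2 against Sin3A. Scaling to one median absolute deviation gave 6702 for RBP2, 0 for Sin3A, 1614 for Sin3B, 35 for Sin3A against Sin3B, 6820 for RBP2 against E2F4, 1 for RBP2 against Sin3A, and 899 and 614 for the H3ac and H3K4me3 changes. With the local median, RBP2 and Sin3A differed at 6 probes. With only the arrays of a mark, H3ac and H3K4me3 changed at 0 probes each, in fits with fewer arrays. Without H3K4me3 differentiated replicate 1 and with the local median, 2346 probes changed in H3K4me3. With an estimated correlation the change at probes bound by E2F4 kept its size (-0.633 for H3ac and -0.359 for H3K4me3, or -0.626 and -0.343 with the local median) and lost the call. A 1.5-fold limit gave 4695 probe sets, since it is less strict.

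The replicate numbers shared by the labels were tested as pairs. Deviations of same-numbered promoter replicates correlated at -0.06, -0.07 and 0.45, those of tiling arrays between -0.36 and 0.48 (median 0.0836 over 18 pairs, against -0.47 to 0.45 between different numbers), and those of the chromatin states between -0.14 and 0.04, so the numbers do not pair the arrays in general. For E2F4 and Sin3B on the promoter arrays (0.45) they mark the software version, a batch that the block takes into account. On the tiling arrays the same-numbered E2F4 and Sin3B arrays correlated at 0.48, 0.25 and 0.11, against -0.36 to 0.25 between different numbers. A pairing of these arrays is therefore not excluded, and the splits of the arrays did not allow for it. With the block, Sin3B and E2F4 differed at 2075 tiling probes. With the replicate block, 774 promoters were bound by E2F4 and 176 by Sin3B, 81, 634 and 588 differed between Sin3A and Sin3B, Sin3A and E2F4, and Sin3B and E2F4, and 81 were called for Sin3A, with 5 differing between the Sin3 proteins, among promoters bound by E2F4. On the tiling arrays the block gave 0 probes for RBP2 and for Sin3A, 2009 and 962 for RBP2 against E2F4 and Sin3B, 652 for H3ac and 11 for H3K4me3, all of which rose. With the block RBP2 was above E2F4 at 0 probes and above Sin3B at 4, and Sin3A was above E2F4 and above Sin3B at 0.

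Leaving out each array in turn gave these ranges, with the deciding arrays named beside each result above. Where no promoter was bound by E2F4, the tests that start from such promoters had nothing to test. Promoters bound by E2F4 ranged from 0 to 485, Sin3A against E2F4 from 0 to 445, Sin3B against E2F4 from 0 to 318, and among promoters bound by E2F4, Sin3A from 0 to 62, Sin3B from 0 to 151 and their difference from 0 to 7. Tiling probes bound by E2F4 ranged from 1600 to 3598, RBP2 from 0 to 6543, Sin3A from 0 to 1408 and Sin3B from 1330 to 4339. Contrasts ranged from 26 to 503 (Sin3A, Sin3B), 1918 to 4825 (RBP2, E2F4), 367 to 2246 (RBP2, Sin3B) and 0 to 24 (RBP2, Sin3A). Changed H3ac ranged from 77 to 2296, H3K4me3 from 0 to 3804 and mononucleosomal DNA from 0 to 8. The mononucleosomal change at probes bound by E2F4 ranged from -0.0528 to 0.110 and was below 0 without cycling replicate 2 (-0.00997), cycling replicate 3 (-0.0528) or differentiated replicate 2 (-0.0252). An arm left with 1 array was assumed to vary like the other groups. The downstream profile on the tiling arrays, expression of bound genes, windows of 5 probes on the tiling arrays and sets from the promoter arrays were not run, because these tables pair no probe with a gene or position here. Inputs were dimmest on E2F4 replicate 2 and Sin3B replicate 2, which limits their values.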

Other observations

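The gene families below were noticed among the promoters bound by E2F4 and tested only after that result was seen, 9 tests in all. Small p-values among them restate that observation and give no independent support. Centromere protein genes stood out, with 11 of 18 Cenp promoters bound against 0.396 expected (Fisher's exact test, adjusted p = 1.26e-13). Core and linker histone genes were bound at 10 of 47 (1.03 expected, adjusted p = 1.78e-07), with members of the H1, H2b, H3 and H4 groups among them. Kinesin genes were bound at 7 of 28 (0.616 expected, adjusted p = 4.23e-06), from Kif15 and Kif18b to Kif2c. Smc genes of condensin, cohesin and their relatives were bound at 4 of 7 (Smc1a, Smc2, Smc4 and Smc6, adjusted p = 1.38e-05), Cdca genes at 3 of 6 (Cdca3, Cdca5 and Cdca8, adjusted p = 3.02e-04) and Mcm genes at 3 of 10 (Mcm3, Mcm5 and Mcm7, adjusted p = 0.00146).

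Zinc finger genes named Zfp were bound at 5 of 250 (Zfp101, Zfp472, Zfp689, Zfp763 and Zfp871), against 5.50 expected (adjusted p = 1), although Zfp689 had the highest ratio among promoters of single genes. Hox genes were bound at 0 of 33 with limma, against 0.727 expected (adjusted p = 1). Promoters shared by divergent gene pairs were bound at 75 of 1444, against 35.3 expected (adjusted p = 1.60e-09). These counts rest on E2F4 replicate 1, without which 0 promoters were bound, and on replicate 2, without which 147 were.

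On the tiling arrays, neighbouring features of the slide correlated at r = 0.364 on E2F4 replicate 3, 0.183 on RBP2 replicate 2 and 0.180 on H3K4me3 differentiated replicate 1, and 30.0% of the features of E2F4 replicate 3 had no ratio. Probe sets for the transferrin receptor had a median expression difference of 0.79 and those for pyruvate carboxylase of 0.23, differentiated over cycling (0.85 and 0.31 with quantile scaling).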
